A study of Mus musculus with 6 samples.

How the data were processed

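Testes of 8-week-old C57BL/6 mice were compared between Gipr knockout animals and wild-type animals, with 3 mice of each genotype per the series design and 1 array per mouse. Gipr encodes the receptor for glucose-dependent insulinotropic polypeptide (GIP), a gut hormone that raises insulin release after a meal and signals through cAMP. Per the labels' protocols, Cy3-labelled cRNA was made from 100 ng of total RNA with a low-input 1-colour kit, so each array carries a single sample and no reference channel.

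The deposited files are the scanner output of Agilent whole-mouse arrays of design 028005. Per the file headers, images were read with Feature Extraction 10.7.3.1, whose processed signal is a background-corrected spot intensity on a linear scale with spatial detrending. The authors also deposited a value list for the same arrays. Set against the scanner files, each of its columns equals the processed signal times a single factor per array that brings the median to 200. Its 46873 entries are the non-control spots well above background on at least 1 array, so these intensity values are linear, uncentred across genes and not ratios. Why that scaling was chosen is not given in the sources used here, and these values served only as an alternative.

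Each array holds 62976 spots, of which 59305 are not controls and read 55681 different probes. Between 70.6% and 76.0% of the non-control spots were well above background, as Feature Extraction defines it, and 0 were saturated. All 6 arrays lie on 1 slide. The knockout samples occupy slide row 1 and the wild-type samples row 2, so slide row and genotype cannot be told apart. On any pair of arrays, at most 0.00169% of the non-control spots held the same value. The number of arrays, 3 per group, limits the precision.

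The log2 of the processed signal was taken, spots that Feature Extraction marked as outliers were left out (117 to 149 per array), the remaining spots of a probe were averaged, and the 75th percentile of each array was subtracted. Values are therefore log2 signal relative to that percentile, and they compare 1 probe between arrays, not different probes with each other. A total of 13 probes had no remaining spot on some array and were dropped. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 38884 probes. Each gene was represented by its brightest tested probe, giving 26933 genes and unnamed transcripts, of which 7804 had more than 1 tested probe.

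Probe names came from the files and were updated through the RefSeq gene table of the GRCm38.p6 assembly, used for names only. An accession matched for 26762 probes, a current symbol for 3819 and a unique older symbol for 639, while 24461 kept the name in the files. Of the tested genes, 16362 had a gene symbol and 10571 had only a predicted-gene name, a transcript identifier or a probe identifier. Probe positions are those in the files, on mouse build mm9 per the file headers, and were given for 26705 tested genes. Exon boundaries on that build were not used here.

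Knockout was compared with wild type in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on all 6 arrays, without covariates. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 counted as a call. Differences are knockout minus wild type on the log2 scale, errors of differences are moderated standard errors (SE), and errors of group means are SD over 3 arrays. A gene not well above background on any array of a group has only a bound there. Its fold is then written as "at least", from the mean of the brighter group and, on each array of the dimmer group, the higher of the gene's own value and the lowest value among probes well above background. With 3 arrays against 3, an exact permutation test of a single gene cannot go below p = 0.1, so the calls rest on the spread that limma shares across genes.

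Genes and lists described by name were chosen by rules fixed before the data were examined. Gipr comes first. Then come up to 12 genes per direction with the largest change among those that passed and whose knockout and wild-type values do not overlap. A direction with fewer was filled with non-overlapping genes of lowest unadjusted p and an absolute log2 fold change of at least 1, which did not pass and are described as such. In each gene list the 4 members of lowest p could be named. Names without a gene symbol counted in totals and gave way to the next gene. Where a gene outside these rules is named, the text says so.

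The 29 gene lists cover testis cell types (spermatogonia, meiotic spermatocytes, round spermatids, elongating spermatids and chromatin condensation, Sertoli cells, Leydig cells, peritubular myoid and smooth muscle cells, macrophages and leukocytes, endothelial cells), tissues a dissection can bring along (blood cells, epididymis, adipose tissue), sperm function (sperm-egg adhesion and fusion, acrosome formation, sperm motility and capacitation, ADAM proteases and partners) and signalling (incretin and islet hormone system, cAMP signalling, CREM target genes, immediate early genes, heat shock and protein folding, interferon response). The others cover metabolism and stress (steroid hormone synthesis, cholesterol synthesis, fatty acid metabolism, glycolysis, apoptosis, oxidative stress) and the genes flanking Gipr on chromosome 7. They were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Lists share members, so their results are not independent of each other.

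A window of 5 Mb on each side of the Gipr probe was also fixed beforehand. The share of calls inside it was compared with that elsewhere by Fisher's exact test, two-sided, and p was adjusted over the window alone as well.

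The fit was tested on simulated arrays with the moderated spread of the real ones, 26933 genes and 5 simulations. It recovered 40.4% of the genes changed 1.414-fold, 86.8% of those changed 2-fold, and 99.2% of those changed 4-fold and of those changed 8-fold. Of its 868 calls, 54 were false (6.22%). Each size had 250 changed genes over the 5 simulations, so a simulation gave many more calls than the 19 of the real arrays. The adjusted threshold is stricter where fewer genes pass, so recovery in the real comparison may be lower than these shares. Camera called a simulated list of 25 genes shifted by 0.25 on the log2 scale in 20 of 20 runs and called 0 of 560 unshifted lists, with simulated genes independent of each other. In the 12 lists that camera called on the real arrays, the estimated correlation between genes ran from 0.07 to 0.76. The 0 of 560 therefore does not give the share of false list calls there.

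The alternatives were normexp background correction (offset 50) of the mean and background signals, quantile normalization, centring on the median, the authors' value table, no filter on dim probes, only probes above background on all arrays, the mean of a gene's probes, eBayes with trend and robust, array weights, the replicate number as a block, and leaving out each array in turn. A slide block was not run because there is 1 slide. A fit without the genes within 15 Mb of Gipr was added after seeing the data. Values were handled with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 (Python 3.11.15).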

Results

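Whole-testis RNA of 3 Gipr knockout and 3 wild-type mice, all 8 weeks old, was measured on 1 array per animal. The series design names a single comparison, testis gene expression with and without the GIP receptor. The arrays resembled each other closely: across 26933 genes, the correlation lay between 0.996 and 0.997 within a genotype and between 0.995 and 0.997 across genotypes, where genes are not independent replicates. The most alike pair crossed genotypes, knockout replicate 2 with wild-type replicate 3 at 0.9971, against at most 0.9969 within a genotype.

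Signal from the targeted gene was lower in every knockout testis. The Gipr probe (NM_001080815) read -2.26 ± 0.12 in the knockout and 0.22 ± 0.19 in the wild type (log2 relative to the 75th percentile, SD, n = 3 each), 5.58-fold lower with a 95% interval of 4.61 to 6.76 (limma adjusted p = 0.00195). On the linear scale its processed signal was 155, 145 and 176 in the knockout arrays and 782, 820 and 1043 in the wild-type arrays, and it stayed well above background on all 6. This probe is the only 1 for Gipr on the array and lies on chromosome 7 at 19742486 to 19742545 (mm9), starting at position 1720 of the transcript per the files. The labels do not say which part of the gene was targeted, so the probe may lie outside it. In that case its fall separates the arrays by label but does not read the deleted part, so it does not show the deletion itself.

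Beyond Gipr, most of the genes that passed lie on the same chromosome, and most of these calls were lower in the knockout, although genes adjusted over a window around Gipr alone went both ways (17 higher, 16 lower), with 0 of the 17 passing over all genes. The 2 largest falls among named genes belonged to Psg19 and Psg18, members of the pregnancy-specific glycoprotein family of secreted immunoglobulin-like proteins. Psg19 fell 23.1-fold, from -1.13 ± 0.05 to -5.66 ± 0.19 (SD, n = 3 each; limma adjusted p = 4.3e-05). Psg18 was not well above background on any knockout array and was at least 9.85-fold lower there (adjusted p = 0.000627). Map4k1, a kinase of blood-forming cells that acts upstream of JNK, fell 9.34-fold, from 3.00 ± 0.04 to -0.23 ± 0.07 (adjusted p = 1.74e-05).

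Over all genes, 19 passed the threshold in limma, 17 lower and 2 higher in the knockout. The count of higher calls depended on the settings, with 8 under normexp or array weights and 12 under eBayes with trend and robust. It was 0 with probes above background on all arrays, with the replicate block, without the genes within 15 Mb of Gipr and in 5 of the 6 fits that left out an array, and 1 without wild-type replicate 1, without a filter on dim probes and with the mean of a gene's probes. An unadjusted p under 0.05 was reached by 2008 genes, against 1347 expected by chance. This count was unstable: 1260 without wild-type replicate 2 and 1294 without knockout replicate 1, both under 1347. It was 3994 without knockout replicate 2 and 5387 with array weights. At the level of single probes, 16 passed as lower and 2 as higher. Of the 19 genes, 12 have a gene symbol, and 16 lie on chromosome 7.

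**Figure D1:**
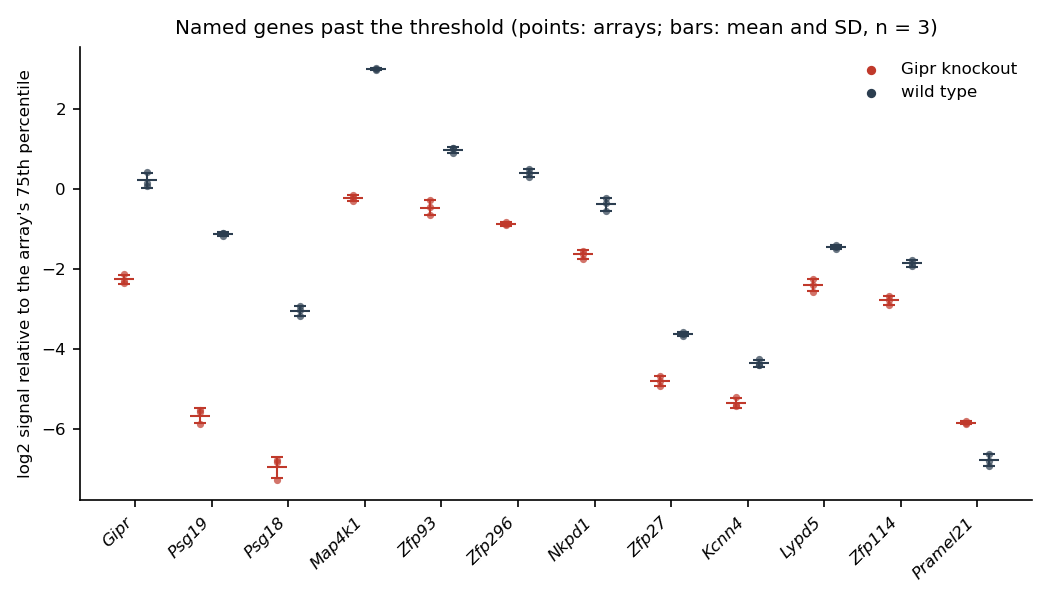
Log2 signal relative to each array's 75th percentile (vertical axis) for the 12 genes with a symbol that passed the threshold; each point is 1 array, with the mean and SD of 3 knockout arrays in red and 3 wild-type arrays in dark blue. The groups are separate for every gene, from Psg19 at -5.66 against -1.13 to Pramel21 at -5.84 against -6.78; the knockout values of Psg18 and the wild-type values of Pramel21 are not well above background.

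Zinc finger genes made up 4 of the other calls: Zfp93 was 2.72-fold lower (limma adjusted p = 0.0182), Zfp296 2.40-fold (adjusted p = 0.00581), Zfp27 2.26-fold (adjusted p = 0.0147) and Zfp114 1.90-fold (adjusted p = 0.0347). Nkpd1, which encodes a protein with a P-loop NTPase domain, was 2.38-fold lower (adjusted p = 0.0312). Kcnn4, a calcium-activated potassium channel, was 1.99-fold lower and Lypd5, of the Ly6 family, 1.94-fold lower (adjusted p = 0.0347 and 0.0438). Each of these 7 genes was lower in 3 of 3 knockout arrays than in any wild-type array. The only named gene that passed as higher was Pramel21 on chromosome 4, of the PRAME-like family, at least 1.72-fold higher and not well above background on any wild-type array (adjusted p = 0.0438).

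Another 7 calls have no gene symbol. Probe A_55_P2137023, on chromosome 7 at 132246864, was 37.0-fold lower (limma adjusted p = 1.92e-06) and was well above background on 1 of 3 knockout arrays and 3 of 3 wild-type arrays. Probe A_55_P2148949, on the same chromosome at 48593869, was at least 4.55-fold higher (adjusted p = 0.0347). The others were lower, and 2 of them lie on chromosomes 14 and 16.

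Genes that did not pass but met the size rule include Psg17, a further pregnancy-specific glycoprotein gene, with -1.48 ± 0.25 (log2, SE; limma adjusted p = 0.336), and Flt4, a growth factor receptor of lymphatic endothelium, at least 1.89-fold lower (adjusted p = 0.596). On the other side stood Fcgbp, an IgG Fc-binding mucin-like protein, with 1.09 ± 0.12 (adjusted p = 0.0837, and under 0.05 in 4 alternatives), and Cyp2g1, an olfactory cytochrome P450, with 1.15 ± 0.29 (adjusted p = 0.596). S100a9, a neutrophil protein, Srpk3, Ano4, Disp2 and Depdc7 had adjusted p from 0.662 to 0.707. Disp2 and Depdc7 did not reach an unadjusted p under 0.05 (limma, 0.109 and 0.174). Disp2 read -3.98 in knockout replicate 1 and -5.95 and -5.97 in replicates 2 and 3. Depdc7 read -3.33 in knockout replicate 2 and -5.86 and -5.82 in replicates 1 and 3. By size alone, 49 genes changed at least 2-fold with an unadjusted p under 0.05, 15 higher and 34 lower, and 24 of them lie on chromosome 7. This count was 18 with normexp, 30 with probes above background on all arrays, 31 without the genes within 15 Mb of Gipr, 81 with array weights, 180 without a filter on dim probes and 75 without knockout replicate 2.

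The number of calls depended on each animal: leaving out knockout replicate 1, 2 or 3 gave 5, 5 and 8 genes, and leaving out wild-type replicate 1, 2 or 3 gave 13, 6 and 6. Gipr, Psg19, Psg18 and Map4k1 passed in every alternative that tested them, Pramel21 in 3 of 16 and the other 7 named genes in 6 to 11 of 16. With normexp background correction, which compresses dim signals, the falls of Psg19, Psg18 and Zfp27 were -2.41, -1.33 and -0.52 on the log2 scale, and Kcnn4 and Pramel21 no longer passed, at -0.29 and 0.09.

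Around Gipr, the genes that passed over all genes were lower, while a less strict adjustment gave changes in both directions. In the window from 14742486 to 24742486 on chromosome 7, 7 of 140 tested genes passed the threshold (6 without Gipr), all 7 lower, against 12 of 26793 elsewhere (Fisher's exact test, p = 4.22e-12). Besides Gipr these were Psg19, Psg18, Zfp296, Nkpd1 and 2 transcripts without a symbol, Gm4567 and ENSMUST00000108446. An unadjusted p under 0.05 was reached by 35.7% of the genes in the window and by 7.31% elsewhere. Adjusted over the window alone, 17 genes were higher and 16 lower, and the lowest adjusted p over all genes among the 17 was 0.111. Without knockout replicate 1, 2 or 3 the window held 3, 3 and 4 calls, and without wild-type replicate 1, 2 or 3 it held 6, 3 and 4.

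The fixed list of genes flanking Gipr also held changes in both directions. Of its 52 measured members, 2 passed over all genes (Zfp296 and Nkpd1) and 19 when adjusted over the list alone. Among those that rose by the second measure were Clasrp, a splicing-related protein, with 0.54 ± 0.06 (log2, SE; adjusted p = 0.111 over all genes and 0.00176 over the list alone), and the phosphatase gene Ppm1n with 0.61 ± 0.08 (0.153 and 0.00238). As a set the list had a median of -0.05 and was not called by camera (adjusted p = 0.128), while the fry mixed test gave an adjusted p of 0.000395.

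**Figure D2:**
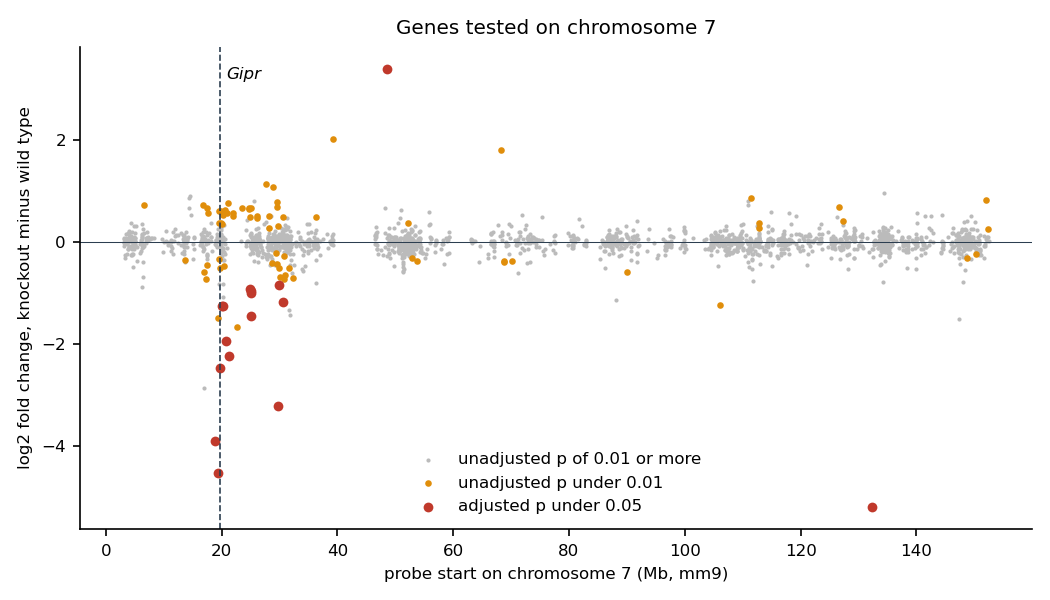
Log2 fold change of the knockout against the wild type (vertical axis) for each tested gene on chromosome 7, by the start of its probe in Mb on mm9 (horizontal axis); red points passed the adjusted threshold, orange points have an unadjusted p under 0.01, grey points neither, and the dashed line marks Gipr. The coloured points lie on both sides of 0 and are densest between 15 and 35 Mb, where 14 of 453 genes passed.

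Markers of spermatids and of several interstitial cell types were on the whole lower in the knockout, and Sertoli and myoid markers higher, by small amounts. Camera called 12 of the 29 lists, 10 lower and 2 higher. With an estimated correlation the same test called 0, with an adjusted p = 0.656 for each of the 12, and fry called 0 by direction. Without knockout replicate 3, camera still called 2 of the 12, Leydig cells and cholesterol synthesis. In 28 of the 29 lists 0 members passed over all genes in limma, so counts of members at an unadjusted p under 0.05 are given instead.

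Leydig cells, which make testosterone, had the largest shift: 20 of 23 markers were lower, with a median of -0.27, and 5 reached an unadjusted p under 0.05 (camera adjusted p = 3.3e-05). Hsd17b3, the enzyme that makes testosterone from androstenedione, read -0.74 ± 0.26 (log2, SE), the adhesion molecule Vcam1 -0.42 ± 0.11 and the prostaglandin D synthase Ptgds -1.58 ± 0.61, with limma adjusted p of 0.662, 0.628 and 0.662. Ptgds overlapped between genotypes, at 6.01 in knockout replicate 2 and 5.73 in wild-type replicate 2. Named outside the rules, the 3 higher markers were Hsd3b1 at 0.16 ± 0.24, Fdxr at 0.03 ± 0.08 and Por at 0.01 ± 0.08. Relative to each gene's mean over the 6 arrays, the median Leydig marker was -0.04, 0.05 and -0.40 in knockout replicates 1, 2 and 3 and 0.10, 0.22 and 0.12 in the wild-type replicates. Without knockout replicate 3 the list had a median of -0.15 (camera adjusted p = 0.00473). Of the 23 markers, 13 are also in another list, and the broader list of steroid hormone synthesis was not called (11 members higher, 14 lower; camera adjusted p = 0.433), with Akr1c14 at 0.29 ± 0.09.

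Genes of cholesterol synthesis were lower for 18 of 24 members, with a median of -0.15 (camera adjusted p = 0.000292). All 7 members with an unadjusted p under 0.05 were lower. Msmo1, a sterol demethylation enzyme, was the only member to pass when adjusted over the list alone, at -0.35 ± 0.06 (log2, SE; adjusted p = 0.0151 over the list alone and 0.274 over all genes). The fry mixed test called this list (adjusted p = 0.00722), and without knockout replicate 3 its median was -0.10 (camera adjusted p = 0.00127).

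Haploid germ cell lists were also lower by camera, but not in every knockout animal. Round spermatid markers were lower for 20 of 23 members (median -0.12; camera adjusted p = 0.00336), with 0 at an unadjusted p under 0.05 and Acrv1, an acrosomal protein, at -0.21 ± 0.09. Elongating spermatid markers were lower for 20 of 24 (median -0.11; adjusted p = 0.00136), with 1 member under 0.05, the sperm tail protein Odf1 at -0.30 ± 0.11. Named outside the rules, the chromatin condensation genes Prm1, Prm2, Tnp1 and Tnp2 hardly moved. They read -0.027 ± 0.066, -0.015 ± 0.069, 0.006 ± 0.072 and 0.002 ± 0.063. Targets of the transcription factor CREM were lower for 17 of 22 (median -0.08; adjusted p = 0.00484), but 19 of them are also in another list. The ADAM proteases and partners, sperm surface proteins and their chaperones, were lower for 19 of 24 (median -0.11; adjusted p = 0.00484), with Adam26a at -0.21 ± 0.08 and Adam25 at -0.26 ± 0.10. Genes of sperm-egg adhesion and fusion were lower for 25 of 38 (median -0.05; adjusted p = 0.0277), with 0 under 0.05. The zona pellucida binding protein gene Zp3r read -0.17 ± 0.08 and Izumo2 -0.20 ± 0.09.

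Knockout replicate 2 did not share the fall of these 5 lists. Relative to each gene's mean over the 6 arrays, its median was 0.09 for elongating spermatids (0.01 to 0.06 in the wild type) and 0.08 for CREM targets (-0.01 to 0.07), above every wild-type array. For round spermatids, ADAM genes and sperm-egg genes it lay within the wild-type range. Without knockout replicate 3 the log2 medians of round spermatids, elongating spermatids, CREM targets, ADAM genes and sperm-egg genes were -0.077, -0.056, -0.026, -0.064 and -0.032 (camera adjusted p = 0.168, 0.160, 0.231, 0.171 and 0.2504). Medians also moved the other way: over the 17 alternatives with a new fit, the lowest were -0.190, -0.180, -0.171, -0.175 and -0.080 in the same order. The round spermatid call also ended without wild-type replicate 2, at a median of -0.053 (0.0721). The sperm-egg call also ended without knockout replicate 1 (-0.056; 0.0658), wild-type replicate 1 (-0.047; 0.0980) or wild-type replicate 2 (-0.038; 0.0721), with quantile normalization (-0.032; 0.104) and without a filter on dim probes (-0.031; 0.123).

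Macrophage and leukocyte markers were lower for 15 of 19 members (median -0.23; camera adjusted p = 0.0089), with Apoe, which lies near Gipr, at -0.34 ± 0.10 and 1 member at an unadjusted p under 0.05. Endothelial markers were lower for 13 of 18 (median -0.09; adjusted p = 0.0278), with Plvap at -0.23 ± 0.08 and 2 members under 0.05. Interferon response genes were lower for 22 of 27 (median -0.07; adjusted p = 0.00484), with Ifit2 at -0.61 ± 0.15 and 3 members under 0.05. Sertoli cell markers were higher for 22 of 28 (median 0.10; adjusted p = 0.00114), with Rhox8 at 0.24 ± 0.07, the FSH receptor gene Fshr at 0.51 ± 0.19 and 3 members under 0.05. Peritubular myoid and smooth muscle markers were higher for 16 of 18 (median 0.15; adjusted p = 0.00484), with the smooth muscle myosin Myh11 at 0.25 ± 0.10 and 1 member under 0.05.

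Knockout replicate 2 did not share the myoid rise or the interferon fall. Its medians relative to each gene's mean, -0.10 and 0.02, lay within the wild-type ranges of -0.12 to -0.04 and -0.01 to 0.12. For macrophage markers, 1 array of each genotype stood apart: relative to each gene's mean, the median was -0.02, 0.00 and -0.30 in knockout replicates 1, 2 and 3 and 0.31, -0.07 and -0.03 in the wild-type replicates. Without knockout replicate 3 the log2 medians of macrophages, endothelium, interferon response, Sertoli and myoid cells were -0.093, -0.052, -0.049, 0.059 and 0.119 (camera adjusted p = 0.240, 0.168, 0.139, 0.139 and 0.145). Over the 17 alternatives with a new fit, these medians went as far as -0.291, -0.114, -0.117, 0.132 and 0.208. Without wild-type replicate 1 they were -0.074 for macrophages (0.249), -0.085 for endothelium (0.0653) and -0.020 for the interferon response (0.216). The endothelial call also ended without wild-type replicate 2 (-0.071; 0.0719) and without a filter on dim probes (-0.095; 0.0719). The macrophage call also ended with array weights (-0.116; 0.180) and without that filter (-0.217; 0.0708). The myoid call ended without knockout replicate 1 (0.065; 0.0906) or wild-type replicate 3, where the median of 0.134 stayed close to the 0.148 of all arrays (0.0839).

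**Figure D3:**
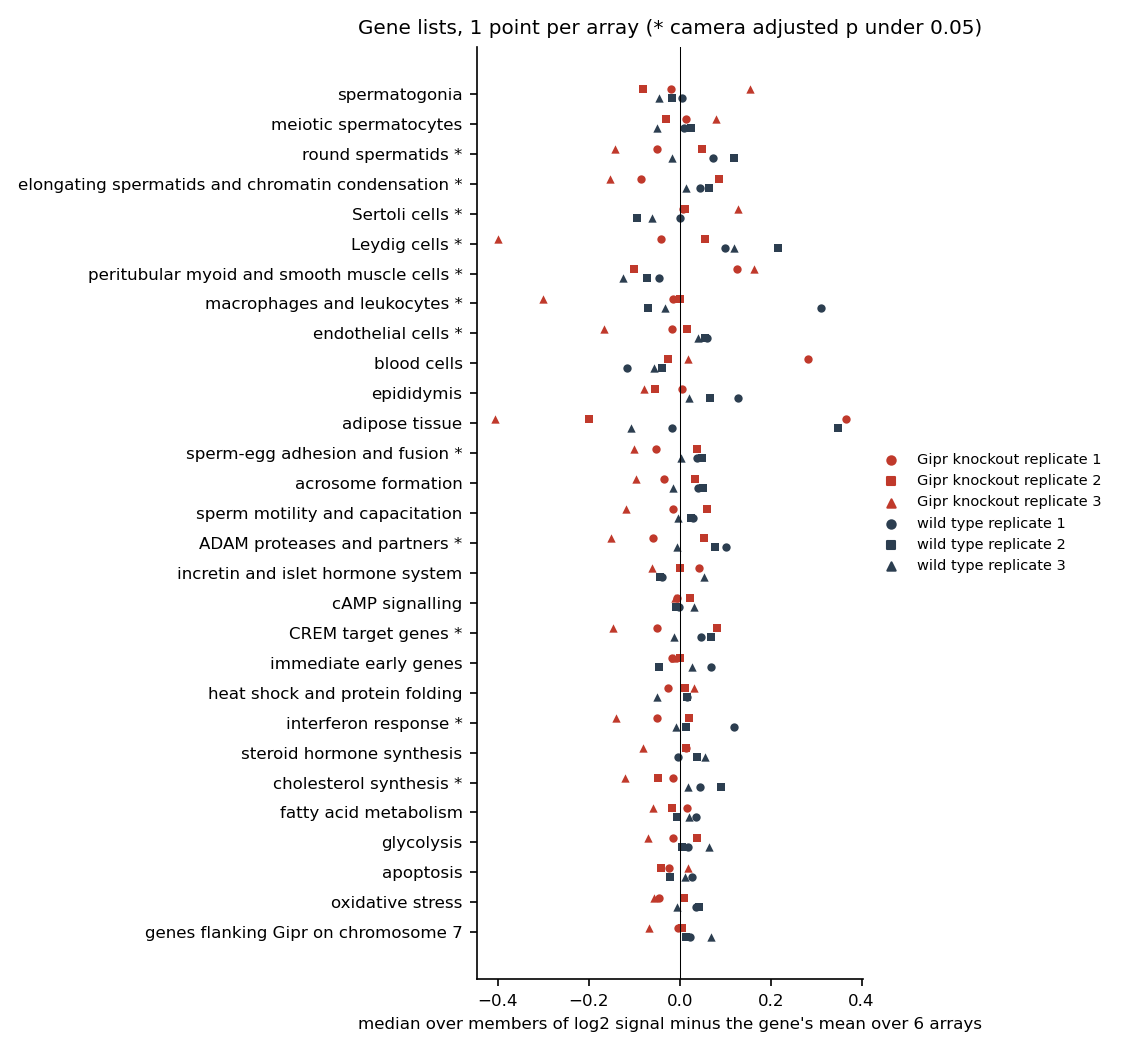
Median over the measured members of each gene list of the log2 signal minus the gene's mean over the 6 arrays (horizontal axis), 1 point per array, knockout in red and wild type in dark blue, with the shape giving the replicate. Asterisks mark the 12 lists that camera called; for Leydig cells, knockout replicate 3 lies at -0.40, while knockout replicates 1 and 2 lie at -0.04 and 0.05.

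The remaining 17 lists were not called by camera, with adjusted p from 0.0618 to 0.841, and in 11 of them the median changed sign under some alternative. Among germ cell lists, 9 of 18 spermatogonial and 22 of 30 meiotic spermatocyte markers were higher (adjusted p = 0.695 and 0.200), with Dmrt1 at 0.14 ± 0.08 and Syce2 at -0.24 ± 0.09. Acrosome formation genes were lower for 18 of 29 and motility and capacitation genes for 28 of 39 (adjusted p = 0.0864 and 0.203), with Spaca5 at -0.28 ± 0.09 and Cfap44 at 0.24 ± 0.08. Camera called the acrosome list without knockout replicate 2 (0.0122) or wild-type replicate 3 (0.0177), with the replicate block (0.0280) and with array weights (0.0231), and the motility list without knockout replicate 2 (0.0146). Epididymal genes were lower for 9 of 14 (adjusted p = 0.128). The receptor kinase gene Ros1 was their only member to pass when adjusted over the list alone, at -0.45 ± 0.09 (limma adjusted p = 0.0358 over the list alone and 0.495 over all genes). Adipose genes were lower for 11 of 17 (adjusted p = 0.237), and their median stood at 0.37 in knockout replicate 1 and 0.35 in wild-type replicate 2, against -0.41 to -0.02 in the other 4 arrays. Camera called the epididymal list without wild-type replicate 3 (0.0432) and the adipose list without knockout replicate 1 (0.00265). Blood cell genes were higher for 6 of 11 (adjusted p = 0.203), and their median stood at 0.28 in knockout replicate 1 and from -0.12 to 0.02 in the other 5 arrays. The haemoglobin genes Hbb-bt and Hbb-bs stood high in knockout replicate 3 as well as 1. Hbb-bt read 2.65, 1.10 and 2.72 in knockout replicates 1, 2 and 3 and 0.98 to 1.59 in the wild type. Hbb-bs read -0.69, -2.04 and -0.86, and -2.29 to -1.66 in the wild type. S100a9 was not well above background on any wild-type array and at least 1.65-fold higher in the knockout, without passing.

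Of the 3 lists set as GIP signalling, camera called only CREM targets, described with the haploid germ cells. The incretin and islet hormone list had 9 members higher and 15 lower (adjusted p = 0.409) and 5 of 24 at an unadjusted p under 0.05. Of these, Pcsk2, a hormone-processing protease, read -0.23 ± 0.07 and the insulin receptor substrate gene Irs2 0.22 ± 0.08. The cAMP signalling list had 18 members higher and 18 lower (adjusted p = 0.841), with the phosphodiesterase gene Pde1a at -0.17 ± 0.06. Immediate early genes were lower for 17 of 27 and heat shock and folding genes higher for 17 of 26 (adjusted p = 0.203 and 0.527), with Btg2 at -0.21 ± 0.11 and Dnajb4 at -0.18 ± 0.10. Fatty acid metabolism genes were lower for 18 of 31, glycolysis genes for 18 of 28 and oxidative stress genes for 23 of 31 (adjusted p = 0.263, 0.200 and 0.0618). Their members of lowest p were Ppargc1a at 0.45 ± 0.11, the aldolase gene Aldoc at -0.56 ± 0.14 and the peroxiredoxin gene Prdx4 at -0.34 ± 0.12, and camera called glycolysis without knockout replicate 2 (0.0457) and oxidative stress with the mean of a gene's probes (0.0317). Apoptosis genes were higher for 15 of 28 (adjusted p = 0.536), with Bbc3, which lies near Gipr, at -0.58 ± 0.15. The sign of the median opposed that of the camera test for spermatogonia, cAMP signalling and apoptosis, all with medians within 0.01 of 0, and that of the mean for the last 2 of these.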

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

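The fit without the genes within 15 Mb of Gipr was chosen only after the results were seen. The lower signal of Gipr kept its direction and passed in every alternative that tested it, from -2.55 to -2.05 (log2). No named gene changed direction in any alternative. The scalings and the authors' values moved the median of all genes by under 0.1, and counts of lower genes, of 2-fold genes, of calls in the window and of called lists not given here stayed within 1.5 times the values above. Except where fewer genes or arrays entered the fit, the cause of a difference was not tested.

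With normexp background 8 genes were higher and 21 lower, and 18 were changed at least 2-fold. Without a filter on dim probes 1 was higher and 6 lower, with 180 changed at least 2-fold and 4 calls within 5 Mb of Gipr, over 34783 genes tested. With probes above background on all arrays 0 were higher and 14 lower, with 30 at 2-fold. The mean of a gene's probes gave 1 higher and 14 lower, eBayes with trend and robust 12 and 22, and array weights 8 and 22 with 81 at 2-fold. Without the genes within 15 Mb of Gipr, 0 were higher, 1 was lower (probe A_55_P2137023) and 31 were changed at least 2-fold, among 26368 genes. The count of gene lists called was 0 by camera with an estimated correlation and 0 by fry by direction, while fry's mixed test called 2. Dim genes are limited by signal over background: Psg18 and Pramel21 have only a bound in 1 group.

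With the replicate block 0 genes were higher and 5 lower, 3 of them within 5 Mb of Gipr, and all 5 were among the 19. The deviations of same-numbered knockout and wild-type arrays correlated at 0.05, -0.05 and -0.03, and only knockout replicate 1 correlated best with its own number, so the numbers were not taken to pair the samples.

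Leaving out each array in turn gave 0 to 1 genes higher, 5 to 12 lower, 46 to 75 changed at least 2-fold, 3 to 6 calls in the window and 2 to 15 gene lists. These fits use 5 arrays. The only higher call was without wild-type replicate 1. Lower calls numbered 5, 5 and 8 without knockout replicates 1, 2 and 3 and 12, 6 and 6 without wild-type replicates 1, 2 and 3. The lowest window counts came without knockout replicates 1 and 2 and wild-type replicate 2, the 75 without knockout replicate 2, and the 2 lists without knockout replicate 3. The calls without wild-type replicate 1 shared 8 genes with the 19, and those without knockout replicate 3 shared 7.

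The median changed sign in some alternative for 11 lists, 0 of them called by camera. For spermatogonia the median was 0.0011 with normexp, 0.014 with the mean of probes and 0.0024 with array weights, and from -0.029 to 0.064 with an array left out. For cAMP signalling it was 0.0058 with normexp, 0.027 with quantile normalization, 0.028 with the mean of probes and 0.010 with array weights, and from -0.0072 to 0.017 with an array left out. For apoptosis it was -0.0042 with normexp, -0.0017 with the authors' values and -0.031 with array weights, and from -0.040 to 0.018 with an array left out. Steroid hormone synthesis stood at 0.00042 with quantile normalization, and blood cells at -0.038 without the filter and from -0.0053 to 0.138 with an array left out. Array weights gave -0.0072 for meiotic spermatocytes, 0.046 for adipose tissue, 0.014 for the incretin list and -0.031 for heat shock. Their ranges with an array left out were -0.012 to 0.056, -0.282 to 0.048, -0.088 to 0.0097 and -0.0032 to 0.038. Sperm motility ranged from -0.092 to 0.00091 and glycolysis from -0.054 to 0.024.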

Other observations

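The tests described here were chosen only after the results they bear on were seen, except the counts over other splits of the samples and the window of 5 Mb, which were fixed beforehand.

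Some vomeronasal receptor genes (Vmn1r family, pheromone receptors) within 5 Mb of Gipr read higher in the knockout testes, and 0 of them passed over all genes. The family was picked after its values were seen. Of its 11 tested members in the window, 10 had a positive log2 fold change, and 6 passed as higher when adjusted over the window alone, with changes from 0.52 to 0.77 and limma adjusted p of 0.157 to 0.549 over all genes. Those 6 were higher in every alternative that tested them, from 0.24 to 0.84, while the count of positive members ran from 8 to 11. Of the 37 tested outside the window, 3 were higher and 0 lower at an unadjusted p under 0.05 in limma. These 3 are among the 11 on chromosome 7, at 5.03, 5.10 and 14.6 Mb from Gipr, and 0 of the 26 on other chromosomes reached it. The sequences of the family are alike, so its probes can read more than 1 member, and the 6 are not independent observations.

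The calls gather on chromosome 7 around Gipr. In 5 Mb bins, set after the data were seen, unadjusted p under 0.01 was reached by 13.5% of 453 genes between 15 and 35 Mb (29 higher, 32 lower) and by 1.35% of genes off chromosome 7. Position on the slide, which is confounded with genotype, has no reason to follow a chromosome. The excess of calls within 5 Mb of Gipr (Fisher's exact test, p = 4.22e-12) argues against it for this pattern. That test counts Gipr itself among 7 calls, 6 without it, and takes neighbouring genes as independent. Slide position stays open for the 3 calls on other chromosomes. It also stays open for probes A_55_P2148949 and A_55_P2137023 on chromosome 7. These lie 28.9 and 112.5 Mb from Gipr, and each is the only call in its bin. An effect of the deletion limited to 1 Mb around Gipr is argued against only as the whole cause. Farther away on chromosome 7 there were 11 calls among 1971 genes, against 3 of 24665 on other chromosomes (Fisher's exact test, p = 1.05e-10). The 11 include probes A_55_P2148949 and A_55_P2137023. Within 1 Mb there were 5 calls, Gipr included, and for its neighbours such an effect stays open. A candidate explanation that stays open and was not tested is that the knockout animals carry alleles of another strain around the targeted gene, since the labels give C57BL/6 for all animals and no history of the targeted cells.

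If the knockout animals carried other sequence under the probes, hybridization could be weaker without any change in RNA. As the whole cause this is argued against by 16 genes within 5 Mb that were higher at an unadjusted p under 0.01, where 1.08 would come from the share on other chromosomes (one-sided exact binomial test, p = 2.67e-14). That count takes 6 Vmn1r genes as independent, and without the family 10 of 129 genes were higher where 0.99 would come (p = 7.94e-08 by the same binomial test, which still takes neighbouring genes as independent). Of the 62 genes other than Gipr within 15 Mb at an unadjusted p under 0.01, 11 had a further probe that does not overlap the first, and in 100% of these it had the same sign (exact 95% interval 71.5% to 100%), with a median ratio of 0.849 to the first; without 2 Vmn1r genes it was 9 of 9 (66.4% to 100%). Lypd5, Zfp114, Zfp27 and Zfp93 are among these 11, with ratios of 0.53, 0.26, 1.07 and 0.82. Other sequence could lie under both probes of a gene that falls, so the same sign does not exclude the explanation for them. Psg19, Psg18, Map4k1, Zfp296, Nkpd1 and Kcnn4 had no further probe tested, so for each of these 6 the explanation stays open as well. Gipr itself has only 1 probe, so other sequence under it stays open for its lower signal too. The same holds for the calls without a symbol Gm4567, ENSMUST00000108446 and 1110035H17Rik, each with 1 tested probe.

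The cell type lists are a second pattern, in which 1 knockout animal may decide the differences. Without knockout replicate 3, camera called 2 lists in all, Leydig cells and cholesterol synthesis, both among the 12. When any other array was left out it called 8 to 15 lists, some of them outside the 12. Of the 18 Leydig markers above the median level of all genes, 15 were lower, 83.3% with an exact 95% interval of 58.6% to 96.4%. This count restates the shift itself and would come from a lower share of Leydig cells as from a lower level per cell, so these cannot be told apart here. Slide row stays open for these lists too.

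The 6 arrays can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For each of the 4 counts only 1 split, the real one, gave a result as large. The real split gave 19 genes past the threshold and the highest other 1, 49 genes changed at least 2-fold and the highest other 24, 7 calls within 5 Mb of Gipr and the highest other 0, and 12 called lists and the highest other 11. The 2 other splits with 11 lists put knockout replicates 1 and 3 together with wild-type replicate 2 or 3. The Leydig median, taken without sign, was 0.275 in the real split and 0.259, 0.253 and 0.228 in the 3 splits that join knockout replicates 1 and 3 with 1 wild-type array.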
